A study of Mus musculus with 12 samples.

How the data were processed

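Bulk RNA-seq was made from brain hemispheres of male mice that lack Lama4, the gene of the laminin alpha 4 chain of vascular basement membranes (Lama4-/-), and of wild-type (WT) mice, all 12 weeks old. Per the labels, the left middle cerebral artery was closed for 60 min with an intraluminal filament and blood flow was then restored for 24 h. The hemisphere on the operated side (ipsilateral) holds the stroke, and the opposite one (contralateral) served as the control without stroke. The mice were perfused with PBS, the olfactory bulb and cerebellum were taken off, and each hemisphere was homogenized whole. Blood and its immune cells were to be removed by centrifugation and washing, per the labels' protocols. The 12 libraries fall into 4 groups of 3, and each library is a pool of 2 mice, so 24 mice stand behind the data. The labels' protocols name a kit for single-cell 3' libraries, although the molecule is given as polyA RNA and the tables hold 1 column per bulk library; which kit made these libraries is left open here.

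The deposited counts are whole reads per gene and library, with no normalization. Per the submitters' processing notes, the tools were bcl2fastq, FastQC 0.72, STAR 2.6.0, featureCounts 1.6.4 and DESeq2 (version not given), on build mm10. Strandedness and gene annotation are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Near-identical genes (Hspa1a and Hspa1b, Amd1 and its copies, Gp49a) carry uncertain counts. Whether related but distinct genes, such as the Ccl family, share reads was not checked. The deposited normalized signal of each hemisphere equals the counts divided by 1 factor per library, between 0.736 and 1.19, set over the 6 libraries of that hemisphere. The deposited fold (ratio) of a gene is the mean of the 3 Lama4-/- over the mean of the 3 WT normalized values, but 11 entries of the contralateral list of lower genes differ from that ratio by over 1%. Each deposited p-value is a Wald p or its adjusted form, per the file headers. The deposited log2 fold changes set Lama4-/- over WT, by the sign of Lama4. The 2 hemispheres were normalized apart by the authors, so all tests here start from the counts. Of the 9 deposited sheets, 6 also hold percent columns per library, 36 in all, which were not used here.

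The count table has 20,347 gene entries, of which 2207 hold 0 counts in all 12 libraries; 19,859 symbols were found in the gene name table. Total counts ran from 27,537,167 to 44,113,824 per library, a ratio of 1.60. At that depth a gene at 1 CPM rests on 27.5 to 44.1 reads. Libraries of the same group correlated at r = 0.990 to 0.996 across genes and differed by more than sampling noise (chi-square over degrees of freedom 9.19 to 32.0), so none was counted as a duplicate. Symbols were taken from the files; coordinates are those of mm10.

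Groups came from the labels. The tests, covariates, gene lists, named genes and alternatives were fixed before the data were examined. The main test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, a robust quasi-likelihood fit and its F test. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Lama4-/- and WT were compared within each hemisphere on its 6 libraries. Ipsilateral and contralateral hemispheres were compared within each genotype, and the difference between these stroke changes (the interaction) was tested, on all 12 libraries with 1 mean per group. Log2 fold changes are given with the standard error (SE), and levels in CPM with the SD over 3 libraries. The p-values between genotypes within a hemisphere measure the spread between pools of mice. Those of the stroke changes and the interaction treat the 12 libraries as independent, although the hemispheres were later taken to be paired by pool.

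The 47 lists of genes hold 577 distinct symbols: vascular matrix and vessel zones, mural and glial cells, leukocytes, neurons by brain region, and response programs. Of these symbols 566 had a gene entry, 6 of them through a synonym, and 44 stand in more than 1 list. The venous and endothelial activation lists share the adhesion genes Icam1, Vcam1, Sele and Selp and also Ackr1, so their results are not separate. Each list with at least 3 tested members was tested with camera (limma 3.58.1) at a preset correlation of 0.01, which compares the list with all other genes; adjusted p was taken over the lists. Camera with an estimated correlation and fry were run beside it. The directional test of fry asks whether the genes of a list move one way on balance, and its mixed test whether they change either way; neither compares a list with other genes. Counts of members are given over all genes tested and adjusted over the list alone.

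The named genes follow a fixed rule. Lama4 is always named. Of the called genes with a mean log CPM of at least 1, no overlap between the libraries of the 2 groups (a condition dropped for the interaction) and a proper symbol, the 10 largest changes in each direction were eligible. Where no gene was called, the 5 smallest p-values were taken and are reported as not passing. From each list up to 4 members with the smallest p were eligible. Genes outside this rule are marked as chosen after their values were seen.

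The labels do not say whether libraries with the same number in both hemispheres come from the same mice, but the text describes both hemispheres of operated brains. Deviations from the group means correlated at 0.109 to 0.337 in all 6 such pairs, and each library correlated best with its own number, so the numbers were taken to pair the hemispheres of 1 pool. A fit with the pool as a block was among the alternatives. Alternatives were other size factors (DESeq2 in edgeR), no filter or a stricter filter on low counts, the replicate number as a block, limma voom with sample quality weights, DESeq2 1.42.0, the other choice of libraries in the fit, stricter thresholds, and leaving out each library. On simulated data with 200 changed genes, the test recovered, at changes of 1.5-fold, 2-fold and 4-fold, 85.1%, 95.5% and 100% for the genotypes in the contralateral hemisphere (14889 genes) and 64.2%, 80.6% and 100% in the ipsilateral one (15111 genes). The shares were 70.1%, 73.1% and 93.9% for stroke in WT (15282 genes), 74.6%, 79.1% and 97.0% for stroke in Lama4-/- (15268 genes) and 46.3%, 73.1% and 92.4% for the interaction (15271 genes), with 5 to 14 false calls per comparison. The simulated genes were drawn independently of each other, with no structure among the libraries beyond the groups. These shares can therefore overstate what the test recovers in the real data, and few calls there do not exclude such changes. Plots were drawn with matplotlib 3.10.9 and the closing tests used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.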

Results

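The study asked how laminins of the vascular basement membrane, the sheet of matrix around every brain vessel, shape the division of cerebral microvessels into arterial, capillary and venous zones. Whole hemispheres of WT and Lama4-/- mice were profiled by RNA-seq after a transient closure of the middle cerebral artery, in 4 groups of 3 libraries. Reads counted in genes ranged from 27537167 to 44113824 in WT contralateral and from 30049032 to 42522384 in Lama4-/- contralateral libraries. They ranged from 35125481 to 39818156 in WT ipsilateral and from 32055487 to 39418282 in Lama4-/- ipsilateral libraries. Between 16567 and 17118 genes had at least 1 read in a library. Mitochondrially encoded genes took 3.51% to 4.72% of the reads.

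Lama4, the targeted gene, was nearly silent in all 6 libraries of the knockout. It encodes the alpha 4 chain that endothelial cells place in the basement membrane (ENSMUSG00000019846, chromosome 10, 38965515 to 39110188, plus strand, mm10). In contralateral hemispheres it stood at 9.18 ± 1.68 CPM in WT and 0.286 ± 0.0705 CPM in Lama4-/- (SD, n = 3), 31.4-fold lower in the edgeR fit. In ipsilateral hemispheres it stood at 14.7 ± 0.167 CPM in WT and 0.532 ± 0.291 CPM in Lama4-/- (SD, n = 3). The raw counts were 198 to 601 in WT and 6 to 33 in Lama4-/- libraries. edgeR gave log2 fold changes of -4.97 ± 0.23 (SE, adjusted p = 2.22e-05) and -4.75 ± 0.28 (adjusted p = 0.00155). After stroke Lama4 rose in WT by 0.67 ± 0.19 (log2, edgeR adjusted p = 0.0326). This call was lost without any 1 of 5 of the 6 WT libraries, with edgeR adjusted p between 0.0753 (without WT ipsilateral replicate 2) and 0.120 (without WT contralateral replicate 2). The other values were 0.103 without WT contralateral replicate 3, 0.0873 without WT ipsilateral replicate 1 and 0.0771 without WT ipsilateral replicate 3. The log2 fold change in these 5 fits was 0.55 to 0.68. In edgeR the call held with the pool as a block (adjusted p = 0.0101) and on the 6 WT libraries alone (adjusted p = 0.00722). It also held in voom (adjusted p = 0.00049) and in DESeq2 (adjusted p = 0.00363).

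**Figure D1:**
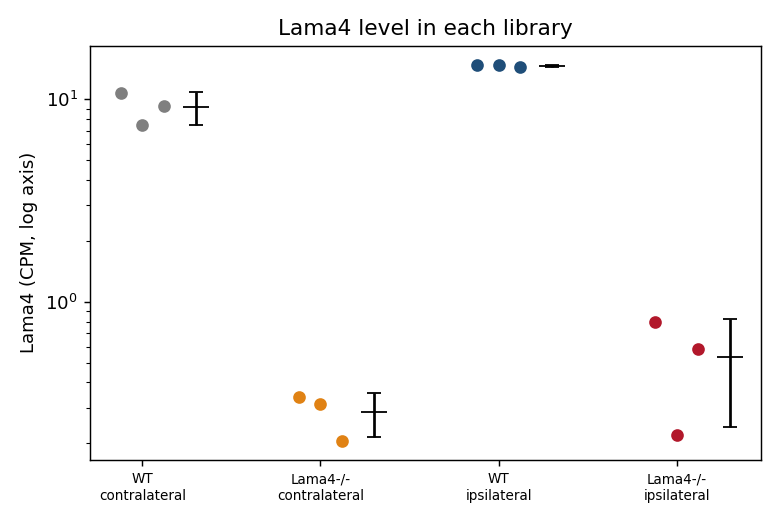
Lama4 expression in CPM on a log axis for each of the 12 libraries, by genotype and hemisphere, with points for libraries and bars for the mean ± SD of 3. The 6 WT libraries lie above the 6 Lama4-/- libraries, whose group means are 0.286 and 0.532 CPM.

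The hemisphere set the main axis of variation among the libraries. The first principal component of 15351 genes carried 59.7% of the variance and the next one 9.94%. All 6 contralateral libraries lay between -34.8 and -25.8 on the first component. WT ipsilateral libraries lay at 22.1, 35.8 and 22.8 and Lama4-/- ipsilateral libraries at 43.1, 36.5 and 22.0. WT ipsilateral replicate 2 thus stood near Lama4-/- replicates 1 and 2, and Lama4-/- ipsilateral replicate 3 near WT replicates 1 and 3.

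**Figure D2:**
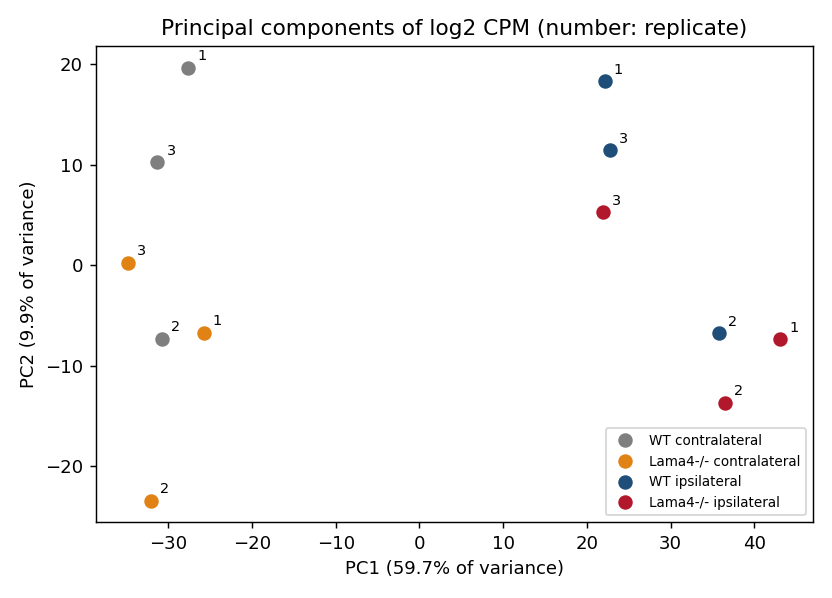
First against second principal component of log2 CPM for the 12 libraries, coloured by group, with 59.7% and 9.94% of the variance on the axes. Contralateral libraries lie at negative and ipsilateral libraries at positive values of the first component.

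Contralateral hemispheres of Lama4-/- and WT mice were compared to see what the missing chain changes in the hemisphere opposite the stroke. All mice were operated, so effects of the operation or of the distant stroke on this hemisphere cannot be told apart from the genotype alone. The lists of genes that neurons and vessels switch on within minutes of a stimulus, and of targets of blood flow and of the coactivator YAP, were called lower in Lama4-/- by camera with its preset correlation, whereas markers of basement membranes and vessel zones passed no test. Both calls were lost at an adjusted p = 0.641 with an estimated correlation, and edgeR called no member of either list. Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227, plus strand), stood at 12.9 ± 0.565 CPM in Lama4-/- and 25.1 ± 3.34 CPM in WT (SD, n = 3). Its log2 fold change was -0.97 ± 0.11 (SE, edgeR adjusted p = 0.0369), and with Lama4 it made up the 2 genes of 14958 that edgeR called. DESeq2 called 17 genes and voom 3, and 1422 genes had an unadjusted p under 0.05 in edgeR, where chance gives 748. The libraries of the groups did not overlap for 2380 genes, 15.9%, where chance gives 10%. Lama4 alone was called without WT contralateral replicate 3 or without any 1 of the 3 Lama4-/- libraries, which left 1 gene, and 9 genes were called without WT contralateral replicate 2.

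The immediate early genes were lower in Lama4-/- for 16 of 16 members tested, with a median log2 fold change of -1.19. Npas4, a transcription factor of active neurons, stood at 7.68 ± 1.40 CPM against 31.8 ± 17.1 CPM in WT (SD, n = 3), a log2 fold change of -2.07 ± 0.49 (SE). Dusp1, a phosphatase that ends MAP kinase signals, had a log2 fold change of -1.19 ± 0.24, Fosb, a partner in the AP-1 factor, one of -1.18 ± 0.28, and Ier2 one of -0.98 ± 0.23. Shear stress and YAP targets had a median of -0.27 over 9 genes, 8 of them lower. Among these, Ccn1, a matrix protein induced by stretch, had a log2 fold change of -1.45 ± 0.37, Klf4, a flow-induced transcription factor of endothelium, -0.81 ± 0.20, and Klf2, its relative, -0.65 ± 0.22. Neurotrophic and regeneration-associated genes had a median of -0.29 over 12 genes, with Bdnf, a neurotrophin, at -0.56 ± 0.14 and Sox11, a factor of growing neurons, at -0.50 ± 0.11. The camera test gave adjusted p = 1.03e-16 for the first of these lists and 6.49e-05 for both others, and adjusted p = 0.641 with an estimated correlation for each. No member of the 3 lists was called by edgeR. Of the immediate early genes 10 had an unadjusted p under 0.05, DESeq2 called 1 and voom 0, and their mean log2 CPM in Lama4-/- replicate 1 (3.99) lay above that in WT replicate 2 (3.95). For the shear stress list the numbers were 5, 1 and 0, and for the neurotrophic list 4, 2 and 0. Adjusted over the list alone, 7, 4 and 3 members were lower. Without WT contralateral replicate 1 the shear stress median was -0.16.

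Camera with its preset correlation called 4 lists higher in Lama4-/-, of mitochondrial subunits, microglia, interferon-stimulated genes and pericytes, and fibroblasts lower. Subunits of mitochondrial oxidative phosphorylation were higher in Lama4-/- for 19 of 20 members, with a median log2 fold change of 0.14 (camera adjusted p = 0.00026, adjusted p = 0.752 with an estimated correlation). That median was 0.09 without WT contralateral replicate 1 and 0.06 without Lama4-/- contralateral replicate 2. Microglial markers had a median of 0.22 (camera adjusted p = 0.00114, adjusted p = 0.646 with an estimated correlation), with C1qb, a complement subunit, at 0.27 ± 0.10 and Trem2, a lipid receptor of microglia, at 0.40 ± 0.16. Interferon-stimulated genes had a median of 0.29 (camera adjusted p = 0.00246, adjusted p = 0.641 with an estimated correlation), with Irf7, a master factor of interferon induction, at 0.66 ± 0.24. With a stricter filter that median was 0.15 (camera adjusted p = 0.0584). Fibroblast markers had a median of -0.14 and pericyte markers one of 0.12 (camera adjusted p = 0.00884 and 0.0483, adjusted p = 0.641 with an estimated correlation for both). Of the pericyte markers, Kcnj8, a potassium channel subunit, stood at 0.56 ± 0.14. Without WT contralateral replicate 2 the medians were 0.06 for microglia and 0.17 for interferon-stimulated genes (camera adjusted p = 0.304 for both), and the camera adjusted p was 0.151 for pericytes. Without Lama4-/- contralateral replicate 3 the medians were 0.11 for microglia and 0.02 for pericytes (camera adjusted p = 0.114 and 0.399), and the camera adjusted p was 0.152 for fibroblasts. For pericytes it was 0.143 without WT contralateral replicate 3 and 0.0709 on all 12 libraries, and their median was 0.19 without Lama4-/- contralateral replicate 2. In voom, camera gave adjusted p of 0.102 for microglia and 0.123 for interferon-stimulated genes. No member of these 5 lists was called by edgeR, and adjusted over the list alone 1 pericyte marker was higher. Related lists had medians below 0 and were not called, with -0.11 for mitochondrially encoded genes, -0.16 for monocytes and macrophages and -0.06 for border-associated macrophages (camera adjusted p = 0.18, 0.17 and 0.581).

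Markers of vessel identity did not pass camera in the contralateral hemisphere. Median log2 fold changes were 0.08 for arterial, 0.02 for capillary, -0.09 for venous and 0.05 for pan-endothelial markers (camera adjusted p = 0.581, 0.342, 0.474 and 0.488). Laminin chains, a list without Lama4, had a median of -0.01 and a mean of 0.02 (camera adjusted p = 0.85). Their alpha 5 and alpha 2 members, Lama5 and Lama2, stood at 0.23 ± 0.10 and 0.19 ± 0.08. Other basement membrane components had a median of 0.03 and laminin receptors one of -0.06 (camera adjusted p = 0.992 and 0.642). Tight junction genes had a median of 0.00, blood-brain barrier transporters one of 0.03 and the Notch pathway one of 0.06 (camera adjusted p = 0.875, 0.391 and 0.54). The arterial connexin gene Gja4, the tight junction gene Cldn5 and the fenestration marker Plvap stood at 0.64 ± 0.17, 0.22 ± 0.12 and 0.45 ± 0.13. Neuron markers had a median of -0.03 and astrocyte markers one of 0.04 (camera adjusted p = 0.761 for both). Median, mean and test direction differed in sign also for cytokines, Wnt targets, angiogenic factors, reactive astrocytes and smooth muscle, each with a camera adjusted p of 0.23 or more.

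Ipsilateral and contralateral hemispheres of WT mice were compared to describe the stroke itself. Cytokines, chemokines, interferon-stimulated genes, heat shock proteins and markers of reactive astrocytes rose in the hemisphere with the stroke. Markers of striatal neurons, which lie in the territory of the closed artery, fell. Hspa1b, an inducible chaperone, went from 6.98 ± 0.257 to 123 ± 41.1 CPM and Hmox1, a heme-degrading enzyme, from 4.55 ± 0.659 to 64.2 ± 26.7 CPM (SD, n = 3). edgeR called 2361 of 15351 genes, 1521 higher and 840 lower, and 582 of these by at least 2-fold (549 higher, 33 lower). With the pool as a block it called 3608 (2024 higher, 1584 lower), and voom called 4542. The count was 1347 without WT contralateral replicate 3, 1485 without WT contralateral replicate 2 and 1561 without WT ipsilateral replicate 2.

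Chemokines and matrix proteases were among the genes that rose in WT. Ccl4 and Ccl3, which draw monocytes, rose by 5.17 ± 0.41 and 4.25 ± 0.27 (log2, SE, edgeR adjusted p = 7.43e-06 and 1.43e-06). Il1rn, the natural antagonist of interleukin 1 receptors, went from 0.0174 ± 0.0153 to 2.79 ± 0.881 CPM (SD, n = 3). Mmp12 and Mmp3, metalloproteases that cleave matrix, rose by 5.42 ± 0.57 and 6.04 ± 0.89, and Ptx3, a soluble pattern receptor, by 5.05 ± 0.57. Of the 19 cytokines and chemokines tested 15 rose, with a median of 3.45 (camera adjusted p = 2.72e-28). Of the 17 interferon-stimulated genes 17 rose, 2.82-fold in the median (camera adjusted p = 9.62e-26), among them Rsad2 by 2.04 ± 0.21 and Irf7 by 1.93 ± 0.21. These were the 2 lists of the WT stroke comparison whose calls held with an estimated correlation (adjusted p = 0.00275 and 0.0365). Of the 13 reactive astrocyte genes 12 rose, with Gfap and Vim, intermediate filaments, up by 1.94 ± 0.21 and 1.93 ± 0.20 and Cd44, a hyaluronan receptor, by 2.83 ± 0.30. Of the 13 heat shock genes 11 rose, and Hspb1, a small chaperone, rose by 3.05 ± 0.29. Of the 10 monocyte and macrophage markers 8 rose, with Msr1, a scavenger receptor, up by 4.17 ± 0.47. The medians of these last 3 lists were 2.62, 0.94 and 2.12, with camera adjusted p of 2.01e-22, 1.97e-16 and 9.47e-11, and adjusted p = 0.0593 with an estimated correlation for each. When adjusted over the list alone, 19, 17, 13, 12 and 8 members of the 5 lists rose.

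Resident glia and macrophages moved in part. Of 15 microglial markers 6 rose and 2 fell, with C1qb up by 1.05 ± 0.12 and Fcrls, a microglial Fc receptor homolog, up by 2.09 ± 0.25 (median 0.50, camera adjusted p = 0.000757, adjusted p = 0.376 with an estimated correlation). Of 10 markers of border-associated macrophages 5 rose, with Mrc1, the mannose receptor, up by 0.68 ± 0.14 (median 0.90, camera adjusted p = 2e-05, adjusted p = 0.135 with an estimated correlation). Of 13 astrocyte markers 4 fell and 1 rose, with the gap junction gene Gja1 down to -0.47 ± 0.09 and the glutamate transporter Slc1a2 to -0.42 ± 0.09 (median -0.32, camera adjusted p = 0.00337, adjusted p = 0.387 with an estimated correlation). No neutrophil marker of 7 was called by edgeR, with a median of 0.53 (camera adjusted p = 0.59), but with the pool as a block edgeR called Cxcr2, a chemokine receptor, and S100a8, the partner of S100a9, as higher (adjusted p = 0.0128 and 0.044). When adjusted over the list alone, 7 microglial, 7 macrophage and 1 astrocyte markers rose, 3 microglial and 6 astrocyte markers fell, and 0 neutrophil markers changed.

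Vascular genes rose in part in WT. Of 14 venous endothelial markers 10 rose, with a median of 0.76 (camera adjusted p = 1.92e-09, adjusted p = 0.0633 with an estimated correlation). Among them Ctsc, a lysosomal protease, rose by 1.41 ± 0.08, Icam1, a leukocyte adhesion receptor, by 1.57 ± 0.26 and Sele, the endothelial selectin, by 2.78 ± 0.53. Of 16 pan-endothelial markers 8 rose, with a median of 0.59 (camera adjusted p = 6.76e-05, adjusted p = 0.387 with an estimated correlation) that was 0.36 without WT ipsilateral replicate 2. Of 9 shear stress and YAP targets 5 rose, with a median of 0.68 (camera adjusted p = 4.88e-05, adjusted p = 0.195 with an estimated correlation), and the mechanosensitive channel gene Piezo1 rose by 1.54 ± 0.12. With the pool as a block Thbd, an anticoagulant receptor among the 5, was not called (edgeR adjusted p = 0.0567). Camera also called the endothelial activation list higher (camera adjusted p = 0.00501). That call was lost with an estimated correlation and with a stricter filter (median 0.20, camera adjusted p = 0.0733). Of 16 capillary markers 3 fell and 1 rose, with a median of -0.33 (camera adjusted p = 0.0277, adjusted p = 0.195 with an estimated correlation). Slco1a4, an organic anion transporter of capillaries, had a log2 fold change of -0.53 ± 0.09. Arterial markers had a median of 0.23 (camera adjusted p = 0.0883), although Tm4sf1, a surface protein of migrating endothelium, rose by 2.05 ± 0.23. Of 9 genes of vesicular transport 5 rose, with a median of 0.34 (camera adjusted p = 0.00328, adjusted p = 0.195 with an estimated correlation), among them Cav1, the caveolar coat gene, by 0.58 ± 0.11. When adjusted over the list alone, 10 venous, 9 pan-endothelial, 6 shear stress, 6 vesicular and 3 capillary genes rose, and 5 capillary genes and 1 vesicular gene fell.

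Matrix genes were divided. Of 17 matrix proteases and inhibitors 9 rose and 1 fell, with a median of 1.01 (camera adjusted p = 1.49e-06, adjusted p = 0.195 with an estimated correlation), and Adamts1, which cleaves proteoglycans, rose by 1.95 ± 0.28. Laminin receptors had a median of 0.17, and Itga7 and Itgb1, integrin chains, rose by 0.73 ± 0.08 and 0.47 ± 0.08. Their camera adjusted p was 0.0215, adjusted p = 0.387 with an estimated correlation, 0.0587 with the pool as a block, 0.0555 in voom and 0.081 without WT ipsilateral replicate 2. Without WT ipsilateral replicate 1 that median was 0.26. Laminin chains had a median of 0.04 and a mean of -0.01 (camera adjusted p = 0.739), and other basement membrane components a median of 0.11 (camera adjusted p = 0.218), with the perlecan gene Hspg2 up by 0.93 ± 0.20. When adjusted over the list alone, 10 proteases and inhibitors and 4 laminin receptors rose and 1 inhibitor or protease fell.

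Striatal neuron markers fell in WT, and other neuronal markers fell in part. Of 13 striatal markers 13 fell, with a median of -0.98 (camera adjusted p = 4.43e-24, adjusted p = 0.0606 with an estimated correlation). Adora2a, the adenosine receptor of indirect pathway neurons, fell by 1.68 ± 0.25, Pde10a, a cyclic nucleotide phosphodiesterase, by 1.12 ± 0.17 and Drd2, a dopamine receptor, by 1.07 ± 0.14. Of 15 general neuron markers 9 fell, with a median of -0.24 (camera adjusted p = 9.4e-05, adjusted p = 0.195 with an estimated correlation), and Syt1, a sensor of vesicle release, fell by 0.33 ± 0.07. Of 11 hypothalamic markers 5 fell, with a median of -0.44 (camera adjusted p = 0.000285, adjusted p = 0.271 with an estimated correlation). Cortical and thalamic markers had medians of -0.15 and -0.17 (camera adjusted p = 0.0965 and 0.112). Choroid plexus markers had a median of -0.51 (camera adjusted p = 0.00133, adjusted p = 0.387 with an estimated correlation), with Enpp2, a lysophospholipase, at -0.53 ± 0.10. Immediate early genes had a median of -0.02 but a mean of 0.48 (camera adjusted p = 0.0883), and 4 of 17 rose, among them Atf3, a stress factor, by 4.26 ± 0.46. The falls adjusted over the list alone took in 13 striatal, 11 neuron, 5 hypothalamic and 6 choroid plexus markers.

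The same comparison in Lama4-/- mice asked how the stroke looks without the laminin chain. The response had the same main parts, with chemokines, reactive astrocyte, interferon and heat shock genes higher and striatal genes lower. Hmox1 went from 5.22 ± 0.516 to 95.7 ± 24.0 CPM and Il1b, the gene of interleukin 1 beta, from 0.207 ± 0.0726 to 1.99 ± 0.293 CPM (SD, n = 3). edgeR called 3580 of 15351 genes, 1969 higher and 1611 lower, and 730 by at least 2-fold (691 higher, 39 lower). The count was 2286 without Lama4-/- ipsilateral replicate 1. The order of the counts in WT and Lama4-/- depends on the method, as voom called 4542 genes in WT and 2898 in Lama4-/-, and edgeR called 2885 and 2470 on the 6 libraries of each genotype alone.

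Of 19 cytokines and chemokines 18 rose in Lama4-/-, with a median of 4.37 (camera adjusted p = 1.02e-34). Of 10 monocyte and macrophage markers 10 rose and of 14 venous markers 11, with medians of 3.43 and 0.99 (camera adjusted p = 6.22e-16 and 9.37e-15). These 3 calls held with an estimated correlation (adjusted p = 0.00206, 0.0406 and 0.0406). Ccl2, a monocyte chemokine, rose by 5.73 ± 0.56, Mmp12 by 6.15 ± 0.52 and Gdf15, a stress cytokine, by 5.24 ± 0.44 (log2, SE). Sele rose by 5.56 ± 0.55, Selp, the platelet and endothelial selectin, by 4.63 ± 0.69 and Icam1 by 2.43 ± 0.27. Of 13 reactive astrocyte genes 13 rose, of 17 interferon-stimulated genes 17, and of 13 heat shock genes 11, while of 13 striatal genes 13 fell. Their medians were 2.52, 1.16, 1.01 and -1.13, with camera adjusted p of 1.04e-19, 3.37e-17, 2.35e-14 and 4.51e-22, and adjusted p = 0.0637 with an estimated correlation for each. Gfap rose by 1.86 ± 0.21, Hspa1b by 4.20 ± 0.41 and Irf7 by 1.53 ± 0.20, and Adora2a and Drd2 fell by 1.76 ± 0.24 and 1.24 ± 0.14. Adjusted over the list alone, 19 cytokines, 10 monocyte, 12 venous, 13 reactive astrocyte, 17 interferon and 13 heat shock genes rose, and 13 striatal genes fell.

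Further vascular lists passed camera in Lama4-/-. Pan-endothelial markers rose for 10 of 16 members, with a median of 0.75 (camera adjusted p = 5.48e-08, adjusted p = 0.224 with an estimated correlation), and the adherens junction gene Cdh5 rose by 1.28 ± 0.23. Shear stress and YAP targets rose for 8 of 9, with a median of 1.03 (camera adjusted p = 1.5e-08, adjusted p = 0.119 with an estimated correlation), and Ccn1 rose by 2.95 ± 0.40. Endothelial activation genes, a list called in WT too, rose for 7 of 12, with a median of 1.39 (camera adjusted p = 6.97e-06, adjusted p = 0.163 with an estimated correlation). Among them Esm1, a proteoglycan of tip cells, rose by 2.33 ± 0.37. Arterial markers rose for 9 of 18 and fell for 1, with a median of 0.47 (camera adjusted p = 0.00783, adjusted p = 0.224 with an estimated correlation) that was 0.30 without Lama4-/- ipsilateral replicate 2. Tight junction genes rose for 7 of 12, with a median of 0.37 (camera adjusted p = 0.0073, adjusted p = 0.31 with an estimated correlation). Laminin receptors rose for 7 of 12, with a median of 0.49 (camera adjusted p = 0.000865, adjusted p = 0.224 with an estimated correlation), and the integrin gene Itga6 rose by 0.76 ± 0.11. Other basement membrane components rose for 6 of 17 and fell for 1, with a median of 0.27 (camera adjusted p = 0.00956, adjusted p = 0.411 with an estimated correlation). Without Lama4-/- ipsilateral replicate 2 that median was 0.16 (camera adjusted p = 0.0938). Col4a1, a collagen chain of the membrane, rose by 1.23 ± 0.20 and Nid1, which links collagen to laminin, by 1.13 ± 0.18. Capillary markers fell for 5 of 16 and rose for 2, with a median of -0.27 (camera adjusted p = 0.022, adjusted p = 0.13 with an estimated correlation), and Ca4, a capillary carbonic anhydrase, fell by 0.74 ± 0.10. Laminin chains had a median of 0.01 (camera adjusted p = 0.877), and 1 of 10, Lamc1, rose by 0.52 ± 0.10. With the pool as a block edgeR also called Lama5 higher (0.40, adjusted p = 0.0337) and Lamc3 lower (-0.46, adjusted p = 0.0345). The p values adjusted over the list alone called 15 pan-endothelial, 9 shear stress, 8 activation, 9 arterial, 7 tight junction, 7 receptor, 7 basement membrane and 2 capillary genes as higher, and 6 capillary, 2 arterial and 1 basement membrane genes as lower.

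Neutrophil markers rose for 4 of 7 in Lama4-/-, with a median of 2.17 and S100a9, a calcium-binding protein of neutrophils, up by 3.10 ± 0.61. Their camera adjusted p was 0.0147, adjusted p = 0.411 with an estimated correlation, and the call was lost without Lama4-/- ipsilateral replicate 1 (0.0748) or replicate 2 (0.131), with a stricter filter (0.425) and on the 6 libraries of the genotype (0.112). The median was 1.06 without Lama4-/- ipsilateral replicate 2, 0.36 with the stricter filter and 0.86 on the 6 libraries. Immediate early genes rose for 6 of 17, with a median of 0.63 (camera adjusted p = 8.93e-05, adjusted p = 0.356 with an estimated correlation) that was 1.14 without Lama4-/- contralateral replicate 1. Fosl1, a late partner in AP-1, rose by 4.48 ± 0.46. General neuron markers fell for 8 of 15, with a median of -0.28 (camera adjusted p = 8.67e-05, adjusted p = 0.156 with an estimated correlation), and Grin1, a glutamate receptor subunit, fell by 0.44 ± 0.07. Microglial and choroid plexus markers had medians of 0.35 and -0.12 (camera adjusted p = 0.144 and 0.33), and pericyte markers a median of -0.30 but a mean of 0.01 (camera adjusted p = 0.679). The p values adjusted over the list alone called 6 neutrophil and 7 immediate early genes as higher and 9 neuron markers as lower.

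**Figure D3:**
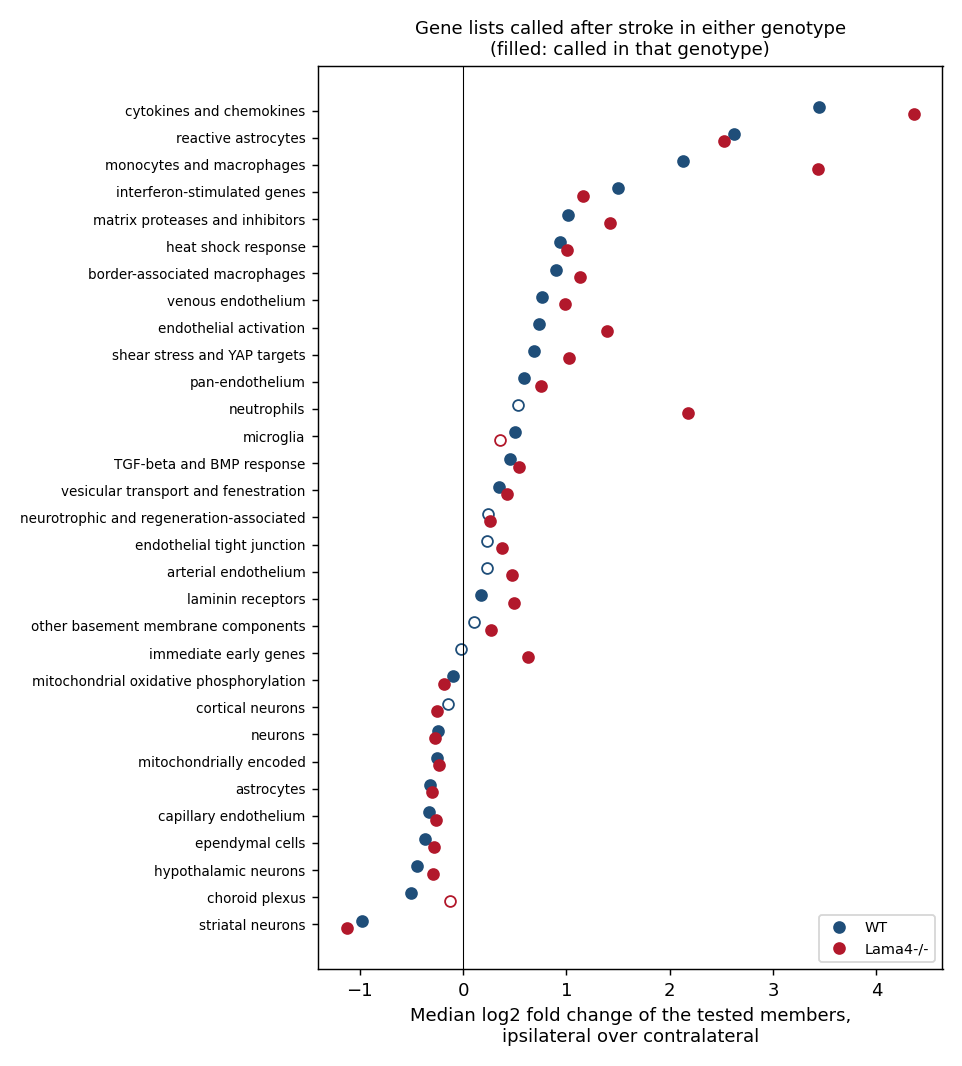
Median log2 fold change, ipsilateral over contralateral, of each gene list called by camera in WT or Lama4-/-, with filled points where the list was called in that genotype. Cytokines and chemokines lie farthest to the right, at 3.45 in WT and 4.37 in Lama4-/-, and striatal neuron markers farthest to the left, at -0.98 and -1.13.

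The stroke changes of the genotypes, which share no library, ran closely together. Across all 15351 genes their log2 fold changes correlated at r = 0.896, and across the 4008 genes called in either genotype at r = 0.936, where genes are not independent replicates. Of those 4008 genes 99.4% had log2 fold changes of the same sign in both genotypes, whether called in both or not. Both genotypes shared 1288 genes that rose, among them Ccl4, Hspa1b, Gfap and Piezo1, where independent lists would share 195, and 645 that fell, among them Drd2, where independent lists would share 88.2. The number of genes called in opposite directions was 0 with edgeR. The slope of Lama4-/- on WT changes was 1.12 by total least squares.

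Ipsilateral hemispheres of Lama4-/- and WT mice were compared to see what the missing chain changes in the stroke. The lists of cytokines, of neutrophil and monocyte markers and of endothelial genes were called higher in Lama4-/- by camera with its preset correlation, and those of immediate early genes and cortical neuron markers lower. All 20 list calls of this comparison were lost with an estimated correlation, where the smallest adjusted p was 0.146, and edgeR called no member of these lists. Il1b stood at 1.99 ± 0.293 CPM against 0.597 ± 0.0391 CPM in WT, Sele at 3.23 ± 1.37 against 1.07 ± 0.119 CPM, and Icam1 at 19.0 ± 3.70 against 12.6 ± 2.33 CPM (SD, n = 3). No single gene other than Lama4 was called by edgeR among 15208 genes. In edgeR 531 genes had an unadjusted p under 0.05, where chance gives 760, and the libraries of the groups did not overlap for 1226 genes, 8.06%, where chance gives 10%. DESeq2 called 20 genes, among them Il1b, Sele, Lyz2, Nr4a1 and Dusp1, and voom 1. edgeR called 2 genes without WT ipsilateral replicate 1, 5 without WT ipsilateral replicate 2, and 3 (Lama4, Ddo and Il1b) in a fit of all 12 libraries, where Ddo, which encodes an oxidase of D-aspartate, is named after its value was seen.

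Of 19 cytokines and chemokines 18 were higher in Lama4-/-, with a median log2 fold change of 0.74 (camera adjusted p = 5.56e-13, adjusted p = 0.146 with an estimated correlation). Il1b had a log2 fold change of 1.73 ± 0.21 (SE, edgeR adjusted p = 0.133) and Ccl7, a monocyte chemokine, one of 0.74 ± 0.19. Il1rn stood at 6.85 ± 2.53 CPM against 2.79 ± 0.881 CPM in WT (SD, n = 3). Neutrophil markers were higher for 7 of 7, with a median of 1.43 and S100a9 at 2.08 ± 0.69. Monocyte and macrophage markers were higher for 9 of 10, with a median of 0.60, Lyz2, the lysozyme of myeloid cells, at 0.58 ± 0.12 and Chil3, a chitinase-like protein of alternatively activated macrophages, at 3.33 ± 2.59 CPM against 0.594 ± 0.0794 CPM in WT (SD, n = 3). Both lists had a camera adjusted p of 1.47e-07 and adjusted p = 0.399 with an estimated correlation. Immediate early genes were lower for 14 of 17, with a median of -0.50 (camera adjusted p = 9.78e-24, adjusted p = 0.146 with an estimated correlation). Nr4a1, an orphan nuclear receptor, stood at 32.4 ± 0.644 CPM against 80.4 ± 21.3 CPM in WT (SD, n = 3), a log2 fold change of -1.31 ± 0.17, and Egr2, a zinc finger factor, had one of -1.22 ± 0.28. edgeR called 0 members of these 4 lists. In edgeR 6 cytokines, 4 neutrophil markers, 6 monocyte markers and 10 immediate early genes had an unadjusted p under 0.05. DESeq2 called 2, 0, 2 and 6 of them and voom 0 in each. Adjusted over the list alone, 4 cytokines and 2 monocyte markers were higher, 10 immediate early genes lower, and 0 neutrophil markers changed. The neutrophil median was 0.86 without Lama4-/- ipsilateral replicate 2, and the monocyte median 0.91 without WT ipsilateral replicate 2.

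**Figure D4:**
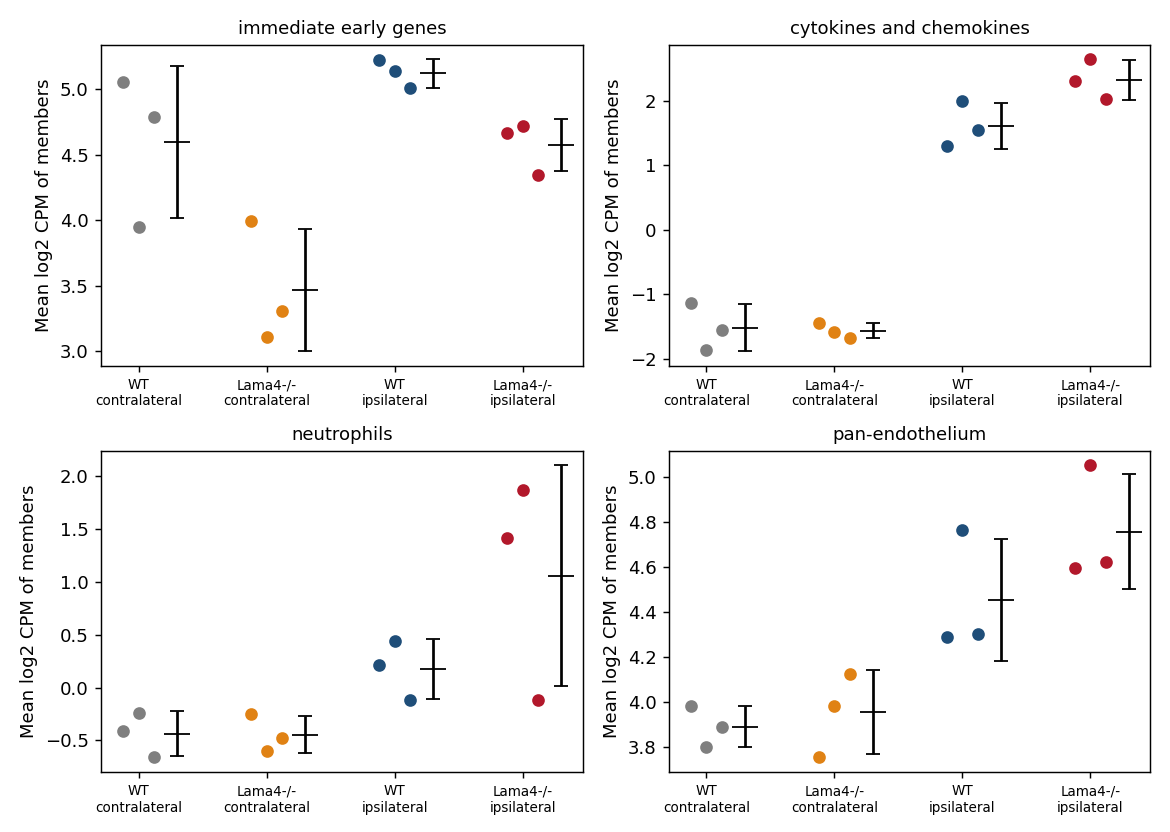
Mean log2 CPM of the members of 4 gene lists in each of the 12 libraries, with points for libraries and bars for the mean ± SD of 3. Among Lama4-/- ipsilateral libraries the neutrophil score was 1.42, 1.87 and -0.12, and the cytokine score averaged 2.33 against 1.61 in WT.

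In the stroke hemisphere camera with its preset correlation called pan-endothelial, activation and venous lists higher in Lama4-/-, but not capillary markers or barrier transporters. Pan-endothelial markers were higher for 16 of 16 members, with a median log2 fold change of 0.30 (camera adjusted p = 1.7e-08, adjusted p = 0.45 with an estimated correlation), among them Clec14a, a lectin of endothelium, at 0.55 ± 0.14 and Tie1, a receptor kinase, at 0.32 ± 0.14. Endothelial activation genes were higher for 11 of 12, with a median of 0.36 (camera adjusted p = 2.39e-08, adjusted p = 0.399 with an estimated correlation), among them Esm1 at 1.02 ± 0.39 and Apln, a peptide of tip cells, at 0.44 ± 0.16. Venous markers were higher for 12 of 14, with a median of 0.25 (camera adjusted p = 1.14e-07, adjusted p = 0.399 with an estimated correlation), among them Sele at 1.58 ± 0.34, Icam1 at 0.59 ± 0.17 and Vwf, the platelet-binding factor, at 0.38 ± 0.15. edgeR called 0 of these genes, 2 pan-endothelial, 5 activation and 5 venous genes had an unadjusted p under 0.05, DESeq2 called 0, 1 and 1, and voom 0 in each. The DESeq2 call was Sele in both lists. As the venous and activation lists share Sele, Selp, Icam1, Vcam1 and Ackr1, the venous call cannot be told apart from one of adhesion genes. Adjusted over the list alone, 2 activation genes and 1 venous gene were higher. The pan-endothelial, activation and venous medians were 0.14, 0.16 and 0.15 without Lama4-/- ipsilateral replicate 2, and 0.49, 0.65 and 0.40 without WT ipsilateral replicate 2. Without Lama4-/- ipsilateral replicate 3 the activation and venous medians were 0.58 and 0.37. The libraries of the genotypes overlapped in the mean log2 CPM of each of these lists. WT ipsilateral replicate 2 lay above Lama4-/- ipsilateral replicate 3 for pan-endothelial (4.77 against 4.62), activation (2.87 against 2.68) and venous markers (4.36 against 4.29). For pan-endothelial markers it also lay above Lama4-/- ipsilateral replicate 1. As that WT library stood near Lama4-/- replicates 1 and 2 on the first principal component, a spread in the size of the stroke stays open here too.

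Arterial markers, other basement membrane components, tight junction genes and laminin receptors had lower medians, of 0.27, 0.17, 0.17 and 0.10. Their camera adjusted p values were 0.000398, 0.000398, 0.00757 and 0.048, with adjusted p = 0.399, 0.496, 0.496 and 0.606 with an estimated correlation. Gkn3, an arterial gene, stood at 1.10 ± 0.42 and Lama2, the laminin chain that astrocytes and mural cells make, at 0.30 ± 0.09. Lama2 lies on chromosome 10 as Lama4 does, with starts 12.0 Mb apart. Without Lama4-/- ipsilateral replicate 2 the 4 camera adjusted p values were 0.104, 0.313, 0.227 and 0.485. The medians of the 4 lists were then 0.13, 0.07, 0.05 and 0.02. The mean log2 CPM of the 4 lists in WT ipsilateral replicate 2 was 2.94, 4.43, 4.43 and 4.58. Each of these values lay above that of Lama4-/- ipsilateral replicate 3, at 2.85, 4.26, 4.33 and 4.42. Without WT ipsilateral replicate 2 the medians of basement membrane, tight junction and receptor genes were 0.25, 0.28 and 0.17, without Lama4-/- ipsilateral replicate 3 those of tight junction and receptor genes 0.26 and 0.17, and without Lama4-/- ipsilateral replicate 1 that of basement membrane genes 0.25. For tight junctions the call was lost also without WT ipsilateral replicate 3 (0.0717), and for laminin receptors without WT ipsilateral replicates 1 (0.0988) and 3 (0.266), without Lama4-/- ipsilateral replicate 1 (0.0682), with no filter (0.0541) and on all 12 libraries (0.0581). Capillary markers, barrier transporters, laminin chains, pericytes and Notch genes had medians of 0.04, 0.05, 0.04, 0.10 and 0.05 (camera adjusted p = 0.799, 0.348, 0.165, 0.108 and 0.127).

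Cortical neuron markers were lower for 11 of 12 members, with a median of -0.24 (camera adjusted p = 3.71e-07, adjusted p = 0.399 with an estimated correlation) that was -0.12 without Lama4-/- ipsilateral replicate 2. Rtn4rl2, a receptor of growth inhibitors, stood at -0.32 ± 0.11. General neuron and thalamic markers had medians of -0.04 and 0.11 (camera adjusted p = 0.104 and 0.298). Camera called hypothalamic and oligodendrocyte markers higher, with medians of 0.21 and 0.09 (camera adjusted p = 0.0395 and 0.00194, adjusted p = 0.632 and 0.496 with an estimated correlation). Without Lama4-/- ipsilateral replicate 2 these were 0.01 and 0.04 (camera adjusted p = 0.74 and 0.152). The hypothalamic call was lost also without WT ipsilateral replicate 1 (0.415) or 2 (0.248), with medians of 0.12, and in voom (0.0789), and the oligodendrocyte call without WT ipsilateral replicate 3 (median 0.05, 0.213). Over the fits without 1 library the medians reached 0.33 and 0.20. Choroid plexus markers, which can come from the lateral ventricle, were higher for 12 of 12, with a median of 0.35 (camera adjusted p = 2.63e-07, adjusted p = 0.399 with an estimated correlation) that was 0.22 without either WT ipsilateral replicate 1 or Lama4-/- ipsilateral replicate 2. Enpp2 stood at 0.33 ± 0.10. Reactive astrocyte, heat shock, microglial and hypoxia genes had medians of 0.14, -0.07, 0.03 and 0.02 (camera adjusted p = 0.18, 0.799, 0.555 and 0.638). Striatal markers had a median of -0.04 and a mean of 0.00 (camera adjusted p = 0.843). Without Lama4-/- ipsilateral replicate 2, heat shock genes and striatal markers were called as higher, with medians of 0.10 and 0.09. Neurotrophic genes had a median of 0.00 but a mean of -0.05 and a downward test (camera adjusted p = 0.0126, adjusted p = 0.399 with an estimated correlation, 0.115 without WT ipsilateral replicate 2, 0.276 without Lama4-/- ipsilateral replicate 3, 0.197 in voom). Inhba, a subunit of activin, stood at -0.87 ± 0.16 (edgeR adjusted p = 0.866), and Vgf, a neuropeptide precursor, at -0.55 ± 0.12. Camera also called matrix proteases, vesicular transport, interferon-stimulated and oxidative phosphorylation genes higher, with medians of 0.20, 0.14, 0.12 and 0.04 (camera adjusted p = 0.000457, 0.00757, 0.0243 and 0.0182, adjusted p = 0.556, 0.399, 0.633 and 0.633 with an estimated correlation). Each of these calls was lost without at least 1 of the libraries, with camera adjusted p up to 0.135, 0.135, 0.797 and 0.14. The lowest medians without 1 library were 0.08, 0.09, 0.08 and 0.03. Those of proteases, interferon-stimulated and oxidative phosphorylation genes also reached 0.34, 0.20 and 0.08. edgeR called no member, also when adjusted over the list alone.

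Whether the stroke changed a gene differently in the genotypes was tested as the interaction. For lists of leukocyte, venous, endothelial activation, cytokine and immediate early genes, camera with its preset correlation called a higher stroke change in Lama4-/- than in WT. These calls were all lost with an estimated correlation, where the smallest adjusted p was 0.188, and edgeR called no gene. For immediate early genes the higher change did not mean a higher level in the stroke. Their median log2 fold change, Lama4-/- over WT, was -1.19 contralaterally and -0.50 ipsilaterally, so it was below 0 in both hemispheres and closer to WT ipsilaterally. Both hemispheres come from operated mice at the same time, so the level before the stroke is not known. Of single genes, Il1b had the smallest p, with a log2 difference of 2.38 ± 0.44 (SE, edgeR adjusted p = 1), as the gene rose by 3.28 ± 0.28 in Lama4-/- and stood at 0.90 ± 0.30 in WT (edgeR adjusted p = 8.09e-06 and 0.0594). edgeR called 0 genes, with 244 at an unadjusted p under 0.05 where chance gives 768, and voom and DESeq2 called 0 each, with 501 and 247 at an unadjusted p under 0.05. Without WT contralateral replicate 2 edgeR called 1 gene, Btg2, an antiproliferative early gene named after its value was seen.

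Camera called 22 lists in the interaction, 18 higher and 4 lower in Lama4-/-, but none of the 22 with an estimated correlation. Monocyte and venous markers had medians of 0.76 and 0.29 (camera adjusted p = 1.21e-07 for both, adjusted p = 0.188 with an estimated correlation). Chil3 and Lyz2 stood at 2.52 ± 1.01 and 0.63 ± 0.21, and Sele and Selp, also members of the endothelial activation list, at 2.78 ± 0.95 and 2.55 ± 1.01. Cytokines and immediate early genes had medians of 0.63 and 0.48 (camera adjusted p = 1.3e-06 for both, adjusted p = 0.188 and 0.48 with an estimated correlation). Ccl7 stood at 1.46 ± 0.63 and Fos, the founding AP-1 member, at 2.19 ± 0.88, as its level went from 10.1 ± 9.82 to 56.2 ± 22.7 CPM in Lama4-/- and from 55.5 ± 29.7 to 67.1 ± 5.35 CPM in WT (SD, n = 3). Endothelial activation and shear stress genes had medians of 0.36 and 0.30 (camera adjusted p = 5.04e-06 and 1.74e-05, adjusted p = 0.365 with an estimated correlation for both), with Ccn1 at 1.64 ± 0.53. The mean log2 CPM of the shear stress genes was 3.32 ± 0.0845 in Lama4-/- against 3.72 ± 0.255 in WT contralaterally (SD, n = 3). Ipsilaterally it was 4.49 ± 0.299 against 4.46 ± 0.182, so their difference lay in the contralateral level. Of the 297 members of the 22 lists edgeR called 0, 22 had an unadjusted p under 0.05, and DESeq2 and voom called 0. Adjusted over the list alone, 1 cytokine differed. Of the 22 calls 15 were lost in at least 1 of the 12 fits that left out a library, and without Lama4-/- ipsilateral replicate 2 camera called 9 lists. The activation, venous and shear stress medians were 0.11, 0.19 and 0.19 without Lama4-/- ipsilateral replicate 2. Without WT contralateral replicate 1 the immediate early, cytokine and shear stress medians were 0.27, 0.34 and 0.16, and without Lama4-/- contralateral replicate 1 the early gene and cytokine medians were 0.73 and 0.98. Without WT ipsilateral replicate 2 the activation and cytokine medians were 0.74 and 0.97, without replicate 1 the venous one 0.19 and without replicate 3 the shear stress one 0.19. Without Lama4-/- ipsilateral replicate 3 the shear stress and cytokine medians were 0.47 and 1.02.

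The authors' deposited table of the contralateral comparison lists 20 genes with an adjusted p under 0.05. Next to Lama4 (-4.99) and Ptgs2 (-0.97) the authors' deposited table holds early response genes with log2 fold changes of -2.25 (Arc), -2.06 (Npas4), -1.46 (Btg2), -1.19 (Dusp1) and -0.98 (Ier2). The authors' deposited table of the ipsilateral comparison lists 5 such genes, Lama4 (-4.76), Ddo (1.06), Il1b (1.74), Chil3 and Amd1 (-0.48), a gene of polyamine synthesis. Ddo (0.99) and Amd1 (-0.42) stand in the contralateral one too. Across the 14886 genes tested in both hemispheres, the genotype changes from edgeR correlated at r = 0.43 across genes, which are not independent replicates, and at 0.40 without Lama4. Of 117 genes with an unadjusted p under 0.05 in both hemispheres 116 went the same way, 83 lower and 33 higher in Lama4-/-, where 47.9 such genes would come up if the hemispheres were independent. The hemispheres come from the same pools, so they are not.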

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

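The list tests of the interaction, the tests of whether 1 library decides the early gene pattern and the counts over other splits of the libraries were planned. All other tests in this part were chosen after the result was seen. The difference between the stroke changes of the genotypes (Lama4-/- minus WT) was tested for each gene list, and camera called 22 lists with the preset correlation, with adjusted p from 1.21e-07 to 0.0454. None of the 22 was called with an estimated correlation, where the smallest adjusted p was 0.188, or by fry, where adjusted p was 0.778 for each. The medians in log2, with their range over the 12 fits without 1 library, were 1.38 for neutrophils (0.53 to 1.88), 0.76 for monocytes and macrophages (0.56 to 1.10) and 0.63 for cytokines and chemokines (0.34 to 1.02). They were 0.48 for immediate early genes (0.27 to 0.73), 0.36 for endothelial activation (0.11 to 0.74), 0.33 for matrix proteases (0.16 to 0.56), 0.30 for shear stress and YAP targets (0.16 to 0.47) and 0.30 for choroid plexus (0.16 to 0.42). Further ones were 0.29 for venous endothelium (0.19 to 0.33), 0.26 for pan-endothelium (0.07 to 0.39), 0.21 for thalamic neurons (0.00 to 0.37), 0.19 for neurotrophic genes (0.04 to 0.33), 0.16 for arterial endothelium (0.02 to 0.33) and 0.15 for fibroblasts (-0.01 to 0.25). The smallest were 0.13 for laminin receptors (0.04 to 0.19), 0.11 for other basement membrane components (0.04 to 0.25), 0.10 for the TGF-beta and BMP response (0.05 to 0.16) and 0.093 for tight junctions (-0.00 to 0.19). Negative differences were found for microglia (-0.20, range -0.29 to -0.13), cortical neurons (-0.13, range -0.22 to -0.07), interferon-stimulated genes (-0.094, range -0.22 to -0.02) and mitochondrial oxidative phosphorylation (-0.084, range -0.14 to -0.00). Of the 22 medians 11 were weakest without Lama4-/- ipsilateral replicate 2, among them those of neutrophils, pan-endothelium and thalamic neurons.

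Leukocyte and cytokine lists had higher medians in the ipsilateral Lama4-/- libraries, with camera calls that were lost with an estimated correlation. These medians could come from a larger injury, from residual blood, from 1 library or from the genotype. Leaving out any 1 library kept the cytokine median at 0.53 or more, but the neutrophil median went from 1.43 to 0.86 without Lama4-/- ipsilateral replicate 2. The neutrophil score of Lama4-/- replicate 3 (-0.12) lay within those of WT (-0.12 to 0.44). The monocyte and macrophage score of that library (3.41) lay below that of WT replicate 2 (3.64). Whether a larger injury raised all induced transcripts alike cannot be told: reactive astrocyte and heat shock genes had a median log2 fold change of 0.06 with an upper 95% bound over genes of 0.14, under the lower bound of 0.38 for the cytokine list, but the cytokine score over theirs parted the genotypes by 0.087 beside an SD of 0.408 between libraries. WT replicate 2 lay with Lama4-/- replicates 1 and 2 on the first principal component (35.8 beside 43.1 and 36.5). That split gave 480 genes, which restates the same structure. Reactive astrocyte scores followed it, at 5.648 to 5.961 in these libraries against 5.055 to 5.515 in the other ipsilateral ones. Striatal scores did not, at 5.03 to 5.49 against 5.17 to 5.57. A spread in the size of the stroke thus stays open. Whether blood was left in the tissue cannot be told either, as the globin gene Hbb-bs had an upper 95% bound of 0.85 and the neutrophil median a lower bound of 0.42, and more leukocyte entry in Lama4-/- stays possible.

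Immediate early genes had lower medians in Lama4-/- libraries of both hemispheres, although contralaterally the score of Lama4-/- replicate 1 (3.99) lay above that of WT replicate 2 (3.95), and this could come from fewer neurons, from the minutes before death, from 1 library or from the genotype. Leaving out 1 library kept the median at -0.98 or lower contralaterally and at -0.36 or lower ipsilaterally, and the neuron list argues against fewer neurons of all kinds, with lower 95% bounds over genes of -0.10 and -0.081 against early gene medians of -1.19 and -0.50. Fewer cortical neurons ipsilaterally cannot be told, as their markers had a median of -0.24 with a lower bound of -0.28, beside -0.04 for striatal, 0.21 for hypothalamic and 0.09 for oligodendrocyte markers. For 11 late-response activity genes, some seen lower before, the upper 95% bound over genes was -0.21 contralaterally and -0.26 ipsilaterally. Their library scores parted the genotypes by 0.198 ipsilaterally (larger SD 0.173) and by 0.030 contralaterally (larger SD 0.208). As part of the set was already known to be lower, these values cannot decide on the last minutes alone in either hemisphere. Longer differences in activity, handling or anaesthesia between the genotypes were not tested. They may account for the lower early gene medians, as may the lack of laminin alpha 4.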

How the results depend on the processing

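All tests in this part were planned, and none was chosen after the result was seen. Lama4 kept its direction and its call between the genotypes under each alternative, between -5.11 and -4.83 contralaterally and between -5.21 and -4.38 ipsilaterally without any 1 library. Of the other results 2556 for lists and 11819 for named genes were the same, 146 and 289 lost a call, 100 and 135 gained one, 145 and 97 changed sign with no call on either side, and 3 list results with a call reversed. The pool as a block took the stroke count in WT from 2361 to 3608 and changed some calls: in WT it lost, for example, laminin receptors (0.0587) and Thbd (0.0567). In Lama4-/- it lost those of hypothalamic, ependymal and neurotrophic lists (camera adjusted p = 0.0706, 0.0706 and 0.0741). Among others it gained Cxcr2 and S100a8 in WT and Lama5 and Lamc3 in Lama4-/-.

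Contralateral genotype calls numbered 1 with a stricter filter, 17 with DESeq2, 1 at an adjusted p under 0.01, 1 at a fold of at least 2, and 1 to 9 without any 1 library. Ipsilateral ones numbered 3 on all 12 libraries, 20 with DESeq2 and 1 to 5 without any 1 library. The labels link replicates of different genotypes by nothing but the number. Their deviations correlated at r -0.097 to 0.349, with 4 of 6 best matched to their own number. The highest value lay above that of the pairs taken as 1 pool (0.337), so a factor shared by replicate number cannot be excluded. Blocking on the number gave 121 contralateral (18 higher, 103 lower) and 4 ipsilateral genes. Stroke calls in WT numbered 4542 with voom, 1073 at an adjusted p under 0.01, 582 at a fold of at least 2 and 1347 to 1740 without any 1 library, and in Lama4-/- 1867, 730 and 2286 to 3618. Interaction calls numbered 0 to 1.

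Lists called with an estimated correlation numbered 0 contralaterally, 0 ipsilaterally, 2 for stroke in WT, 3 for stroke in Lama4-/- and 0 for the interaction. With the directional test of fry they numbered 0, 0, 24, 30 and 0 in the same order. With the preset correlation and without any 1 library the counts were 5 to 12, 14 to 25, 22 to 27, 25 to 30 and 9 to 29. The striatal list reversed ipsilaterally, to 0.11 without WT replicate 3 and 0.09 without Lama4-/- replicate 2, with a lowest value of -0.10. The heat shock list reversed to 0.10 without Lama4-/- ipsilateral replicate 2, with a lowest value of -0.13. Stricter thresholds lower a count by construction, and for all other changes the cause was not tested. At the lowest depth a gene at 1 CPM rests on 27.5 reads, which limits Il1b, Sele and the neutrophil genes in contralateral libraries.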

Other observations

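The tests on Ddo in this part were chosen after the result was seen, and the counts over other splits of the libraries were planned. Ddo, Amd1 and the genes of the Y chromosome are named after their values were seen. Ddo encodes an oxidase of D-aspartate and starts 1.66 Mb from the start of Lama4 on chromosome 10 (40630011 to 40681847, plus strand). Amd1, a gene of polyamine synthesis, lies between them (40287458 to 40302186, minus strand). Ddo stood at 12.9 ± 1.04 CPM in Lama4-/- and 6.45 ± 0.994 CPM in WT contralateral libraries, and at 11.7 ± 1.66 and 5.60 ± 0.376 CPM in ipsilateral ones (SD, n = 3). Its edgeR adjusted p was 0.121 contralaterally and 0.133 ipsilaterally, while DESeq2 called it in both hemispheres. Amd1 stood at 31.5 ± 1.68 against 41.8 ± 2.62 CPM and at 25.8 ± 2.08 against 36.1 ± 3.47 CPM (SD, n = 3).

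The Ddo difference could come from 1 library, from a chromosome segment of another strain kept around the deleted gene, or from the loss of Lama4 itself. It does not rest on 1 library, since the lowest Lama4-/- value lay at least 3.77 CPM above the highest WT value in both hemispheres. Within 2 Mb of Lama4, 2 of 18 genes differed in both hemispheres with the same sign (unadjusted p under 0.05), namely Ddo and Amd1, against 112 of 14581 genes elsewhere. Without these genes, which prompted the idea, the smallest adjusted Fisher p over 6 windows of 1 to 30 Mb, across genes that are not independent replicates, was 0.513, so the segment can be neither held nor dropped. In the window of 20 Mb, 3 of 135 genes other than Ddo and Amd1 differed in this way (2.22%), against 109 of 14462 elsewhere (0.754%). These were Lama2, Col10a1 and Tmem200a, at 12.0, 4.58 and 13.1 Mb from Lama4, the last 2 named after their values were seen. Strain variants were not analysed here.

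Splits of the 6 libraries of each comparison, or of the 6 pools for the interaction, into other groups of 3 number 10 with the real one, too few to go under a share of 0.1. Counting the real split, as many genes were called in 1 split for the contralateral comparison (2 against at most 0 elsewhere), 3 for the ipsilateral one, 1 for stroke in WT (2361 against 0), 1 for stroke in Lama4-/- (3580 against 0) and 10 for the interaction (0 against 0), by edgeR. The ipsilateral split that set WT replicate 2 with Lama4-/- replicates 1 and 2 gave 480 genes against 1 for the real split, so structure of the samples other than genotype is the larger one there. As many lists were called by camera in 6, 3, 3, 2 and 2 splits. The real counts of 8, 20, 24, 29 and 22 lists are not above the highest of other splits, 12, 26, 25, 29 and 24.

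Eif2s3y, a gene of the Y chromosome, stood at 18.2 and 13.7 CPM in the contralateral and ipsilateral libraries of Lama4-/- replicate 3 and at 41.8 to 59.0 CPM in the 10 others. In the same pair of libraries Ddx3y stood at 72.1 and 89.3 CPM, against 75.9 to 112 CPM elsewhere. Of the other Y chromosome genes, Uty in this pair lay within the range of the other libraries, and Kdm5d lay a little below it. Whether 1 of the 2 mice of that pool could lower Eif2s3y this far was not tested, and the cause stays open. The pool also stood apart from the other Lama4-/- pools ipsilaterally, at 22.0 against 43.1 and 36.5 on the first principal component and at a neutrophil score of -0.12 against 1.42 and 1.87, so it bears on the genotype comparisons. Without it edgeR called 1 gene, Lama4, in each hemisphere, and 1776 contralateral and 1070 ipsilateral genes had an unadjusted p under 0.05. The authors' deposited lists of contralateral genes hold 111 entries for higher and 95 entries for lower genes, the latter for 86 distinct genes.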
